A study of Homo sapiens with 47 samples.

How the data were processed

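Small RNA was sequenced from 2 human prostate cancer cell lines. PC-3, per the labels, comes from a bone metastasis, and 22Rv1 is a line that expresses the androgen receptor. Cells were grown in RPMI-1640 with 10% serum and kept for 24 h in a hypoxia chamber at 5, 2, 1, 0.5, 0.2 or 0% O2, with normoxia (95% air) controls belonging to each level. Every group had 2 libraries, except the 22Rv1 normoxia control of the 0.2% level, of which 1 was used here, giving 24 PC-3 and 23 22Rv1 libraries in 24 groups. Total RNA was prepared with the miRNeasy kit, libraries with the TruSeq Small RNA kit, and fragments of 140 to 160 bp were taken from the gel. The submitters' processing notes name FastQC for read quality and hg19 as the genome. The aligner and the counting tool are not given in the sources used here.

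The deposited count table holds whole-number read counts per mature miRNA, 1006 entries in 47 libraries. The authors' second table holds CPM (counts scaled to a common library total), adjusted by the trimmed mean of M values (TMM). Each of its columns was checked to be the counts times 1 constant per library, with a relative difference of at most 2.6e-09. The implied scaling factors ran from 1.01 to 1.95. The tests here used the counts, and the authors' factors served as an alternative. Of the 1006 entries, 24 formed 9 sets with identical counts in every library. Every entry had a total of at least 22 counts and was seen in at least 12 libraries, so entries below that are not part of the table. Raw reads were not analysed here.

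Library totals ran from 960421 to 4327382 counts (median 2649735). The 5 most abundant miRNAs took 38.2 to 53.0% of a library, which leaves low-abundance miRNAs with few counts. Replicates differed by more than counting error, with a chi-square per degree of freedom of at least 27.9 between the 2 libraries of a group. The common biological coefficient of variation was 15.3% in PC-3, 17.7% in 22Rv1 and 16.9% over both.

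Counts were analysed in R 4.3.3 with edgeR 4.0.16. miRNAs with at least 5 CPM in at least 2 libraries were kept (463 in PC-3, 552 in 22Rv1, 613 over both lines), libraries were scaled by TMM, and a model with 1 mean per group was fitted with robust quasi-likelihood dispersion. Within each line the contrasts were hypoxia against its own normoxia control at each level, the mean of these 6 effects, their linear trend over the 6 ordered levels (log2 per step toward lower O2), and an overall test of differences between the normoxia control sets. Over both lines the contrasts were the difference of the mean effect (PC-3 minus 22Rv1) and PC-3 against 22Rv1 in normoxia. In the 22Rv1 control of the 0.2% level the single library is assumed to vary like the other groups. A miRNA was called at a Benjamini-Hochberg adjusted p below 0.05. Because each level has its own controls, no control library enters 2 levels. CPM in the text are TMM scaled, and plus-minus values are SD between libraries. Tests were two-sided.

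The 18 miRNA lists were written from general knowledge before the data were examined. They were the hypoxia-induced list from the literature, miRNAs reported to target HIF1A, miR-17~92 and paralogues, miR-232724, let-7/miR-98, miR-200/141/429, miR-15/16, miR-29, miR-30, p53-regulated miRNAs, androgen receptor-linked miRNAs, mesenchymal or basal-associated miRNAs, the chromosome 14 cluster, the chromosome 19 cluster with its neighbour miR-371, smooth muscle or stromal markers, blood or serum markers, neuronal markers and entries overlapping other RNA classes. Lists name miRNAs without the arm, so both arms of a hairpin counted as members, whether or not the reports behind the list concerned that arm. The last list, meant as a sign of RNA quality, includes miR-4521, miR-1260a, miR-1260b and miR-4485. Lists share members: miR-27a, for example, is in the hypoxia-induced, miR-232724 and androgen receptor-linked lists. Each list with at least 3 tested members was compared with the other miRNAs by camera (limma 3.58.1) with a correlation of 0.01, and again with the correlation estimated from the data. Members were also adjusted over their list alone, and the counts given as over the list alone come from that.

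The miRNAs named were picked by a rule set before the data were examined. For the mean effect these were up to 10 per direction by fold among called miRNAs with at least 20 CPM and the same sign in at least 5 of 6 levels. For a single level they were up to 2 per direction, for the trend and the line difference up to 5, and for normoxia up to 10, all with at least 20 CPM. Both arms of miR-210 were always given, with up to 4 members per list by smallest p and the 5 most abundant miRNAs per line. miRNAs named beyond this, such as miR-4461, miR-551b-5p, the shared calls of the lines and miR-143-3p, were chosen after the values were seen. Gene positions and host genes are from GENCODE 29 on GRCh38, matched by name for 980 of the 1006 entries, and are given as chromosome and host or neighbouring gene (within 10 kb).

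The contrasts, the main model and most alternatives were fixed before the data were examined. These alternatives were DESeq2 size factors in edgeR, scaling by library size alone, no low-count filter, a filter at 50 CPM, DESeq2 1.42.0, all normoxia libraries of a line as the control of each level, the replicate number as a block within line and level, a trend without the 0% level on a log2 scale of O2, a trend over the hypoxia libraries alone, estimated list correlation, and the omission of each library in turn. The authors' scaling factors, identical entries kept once, and the omission of libraries apart on the first principal component were added after the data were seen. Where a call is said to be kept or lost in so many alternatives, the omissions of single libraries are not among them and are given apart.

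Hypoxia and normoxia libraries of a level carry the same replicate numbers, so it was checked whether these pair the libraries. The residuals of the hypoxia and normoxia library with the same number correlated across miRNAs at every level with 2 control libraries, with r from 0.302 to 0.857 in PC-3 and from 0.116 to 0.641 in 22Rv1, and between -0.04 and 0.06 when the 2 lines were compared. Libraries of a level with the same number therefore share deviations, and they are called pairs here. A difference between the replicate numbers across all levels of a line would give this too, and the check does not tell these apart. Values with the replicate number as a block are given beside many counts and calls that they change.

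The code was tested on simulated counts with the depth and dispersion of these libraries, with 100 miRNAs changed by 1.5-fold and 100 by 2-fold. For the mean effect in PC-3 it recovered 91% and 96% of them, with 6.5% of calls false, and in 22Rv1 81% and 95%, with 1.7% false. At a single level (0% O2) it recovered 51% and 74% in PC-3 and 13% and 54% in 22Rv1, and for the line difference 55% and 61%. Of 40 unchanged lists in each line 0 had a camera p below 0.05. The simulated counts were drawn independently for each miRNA and library. They hold no correlation between list members and no pairing of libraries, so the check cannot cover either.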

Results

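MicroRNA (miRNA) levels were measured by small RNA sequencing in 2 human prostate cancer cell lines, PC-3 and 22Rv1, after 24 h at 5, 2, 1, 0.5, 0.2 or 0% O2. Each O2 level had its own normoxia control (95% air). The 24 PC-3 libraries held 1742290 to 4327382 counts and the 23 22Rv1 libraries 960421 to 3181344, over 1006 miRNA entries. In PC-3 the 5 most abundant miRNAs were miR-21-5p (13.7% of counts), miR-191-5p (10.2%), miR-182-5p (8.19%), let-7a-5p (7.47%) and miR-22-3p (3.81%). In 22Rv1 they were miR-191-5p (16.3%), let-7a-5p (9.47%), miR-182-5p (7.15%), miR-148a-3p (6.04%) and miR-16-5p (4.20%). The labels do not say whether the replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

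miR-210 is transcribed under direct control of hypoxia-inducible factor, and its gene lies in MIR210HG on chromosome 11 (GENCODE 29, GRCh38). Both of its arms rose in both lines. In PC-3, miR-210-3p was at 575 ± 75.4 CPM (mean ± SD, n = 12) in normoxia and at 932 ± 96.9 CPM (n = 12) in hypoxia. Averaged over the 6 O2 levels it rose 1.62-fold (log2 0.70, standard error 0.064, adjusted p = 1.1e-07, edgeR quasi-likelihood test), with the hypoxia library higher in 12 of 12 pairs. In 22Rv1 it went from 1347 ± 166 CPM (n = 11) to 2747 ± 454 CPM (n = 12), 2.02-fold (log2 1.01, standard error 0.073, adjusted p = 2.8e-09), and was higher in 11 of 11 pairs. The less abundant arm, miR-210-5p, rose 1.61-fold in PC-3 (log2 0.68, standard error 0.076, adjusted p = 1.6e-06, 63.7 ± 10.8 to 102 ± 18.3 CPM). In 22Rv1 miR-210-5p rose 2.96-fold (log2 1.57, standard error 0.13, adjusted p = 3.7e-08, 105 ± 23.1 to 317 ± 113 CPM). The difference between the lines passed the test for miR-210-5p (PC-3 minus 22Rv1, log2 -0.90, adjusted p = 9.3e-05) and not for miR-210-3p (log2 -0.34, adjusted p = 0.084). For miR-210-3p it passed in 3 of 9 alternatives, among them the replicate block (adjusted p = 0.0072, range 0.0072 to 0.353).

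**Figure D1:**
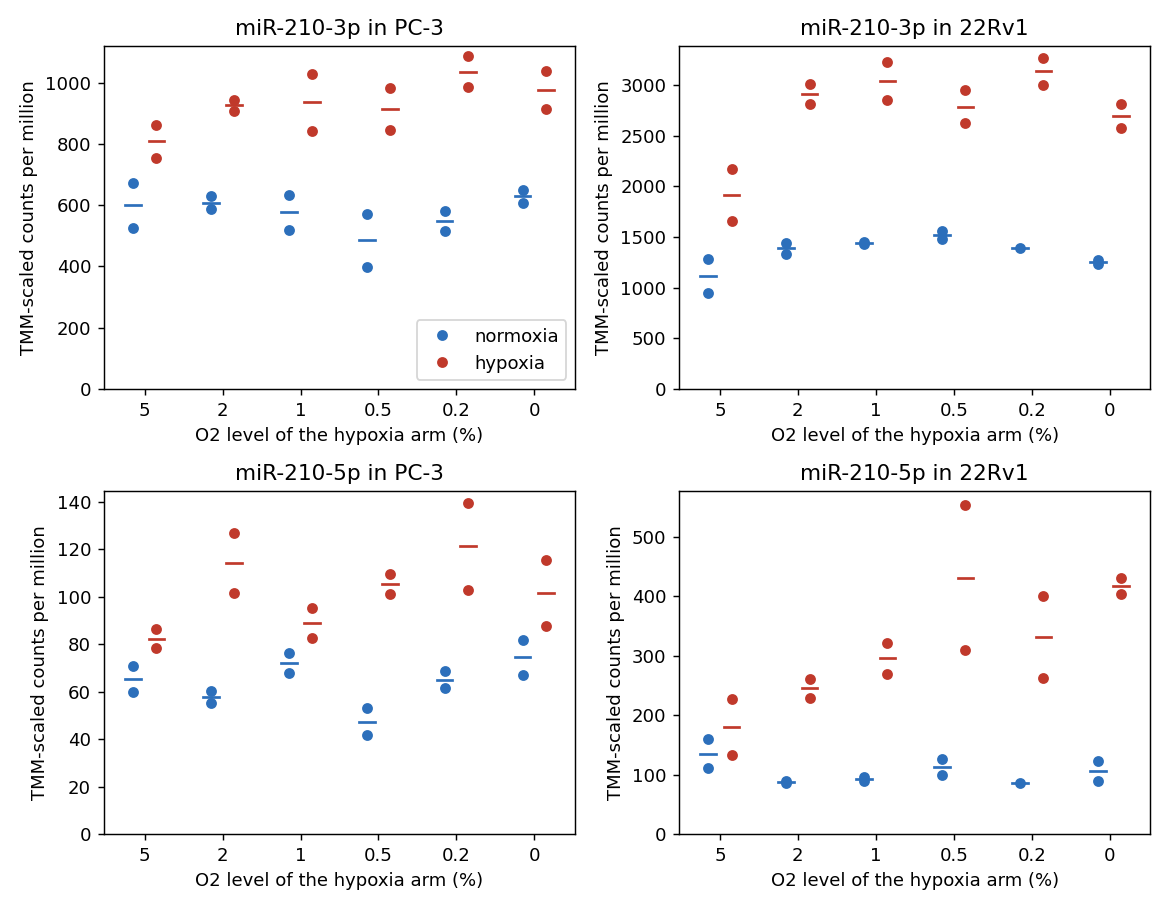
Both arms of miR-210 against O2 level, in CPM (TMM scaled), for PC-3 and 22Rv1, with single libraries as points in normoxia and hypoxia and the normoxia libraries at each level being its own controls. In PC-3 miR-210-3p was higher in the hypoxia library in 12 of 12 pairs, and in 22Rv1 in 11 of 11.

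Level by level, the effect on miR-210-3p in PC-3 was log2 0.43 at 5% O2, 0.61 at 2%, 0.70 at 1%, 0.91 at 0.5%, 0.92 at 0.2% and 0.64 at 0%. It passed the test at 1% (adjusted p = 0.0416), 0.5% (0.00192), 0.2% (0.00328) and 0% (0.0259), and missed it at 5% (adjusted p = 0.998) and 2% (0.0556). With the replicate number as a block the adjusted p at 5% and 2% O2 was 0.032 and 2e-04. Over all alternatives it ranged from 0.032 to 1 at 5% and from 2e-04 to 0.0685 at 2%. The call at 1% was lost in 5 of 10 alternatives (adjusted p up to 0.138) and that at 0% in 2 (up to 0.142, with the authors' factors), and those at 0.5% and 0.2% in none. Without 1 library of the level, which is counted apart from these alternatives, the calls at 1, 0.5, 0.2 and 0% were kept in 0, 2, 1 and 0 of 4 omissions. In 22Rv1 the effect was log2 0.78 at 5% O2, 1.07 at 2%, 1.08 at 1%, 0.88 at 0.5%, 1.17 at 0.2% and 1.11 at 0%. The 22Rv1 change passed the test at every level but 5%, where the adjusted p was 0.090 (0.043 with the block, 0.0026 with DESeq2, range 0.0026 to 0.998). Each of these calls was lost with scaling by library size alone (adjusted p up to 0.259) and in no other of the 10 alternatives. Without 1 library the calls at 2, 1, 0.5 and 0% were kept in 3, 2, 3 and 4 of 4 omissions, and that at 0.2% in 2 of 2.

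Averaged over the 6 levels, hypoxia changed 51 of 463 tested miRNAs in PC-3, 27 higher and 24 lower, and 109 (51 higher, 58 lower) with the replicate block. The 51 were among the 109. With scaling by library size alone 66 were called, 22 higher and 44 lower. Besides miR-210, the largest rises among miRNAs with at least 20 CPM and the same sign in at least 5 of 6 levels were in miR-3919 (1.68-fold, log2 0.75, standard error 0.12, adjusted p = 9.5e-05, higher in 12 of 12 pairs), miR-193b-3p (1.52-fold, log2 0.60, adjusted p = 0.00089, 11 of 12 pairs), miR-30b-3p (1.47-fold, log2 0.56, adjusted p = 0.00027, 12 of 12 pairs) and miR-125a-3p (log2 0.52, adjusted p = 6.1e-05). The neighbouring miR-30d-5p, an abundant miRNA, rose from 19568 to 25851 CPM (log2 0.40, adjusted p = 5.8e-05, 12 of 12 pairs), with miR-30d-3p (log2 0.40). From the miR-181c/181d hairpins on chromosome 19, miR-181c-3p and miR-181d-5p both rose (log2 0.37 each, adjusted p = 5.8e-06 and 1.9e-06). By the same rule the largest falls were in miR-92a-1-5p (log2 -0.60, adjusted p = 7e-05, lower in 11 of 12 pairs), miR-4521 (log2 -0.58, 11 of 12 pairs), miR-222-5p (log2 -0.57, adjusted p = 1.3e-05), miR-27b-5p (log2 -0.49), miR-128-1-5p (log2 -0.46, 12 of 12 pairs) and miR-181a-3p (log2 -0.46, adjusted p = 0.0047, 12 of 12 pairs). miR-188-5p (log2 -0.46), miR-25-5p (log2 -0.42), miR-29b-1-5p (log2 -0.34) and miR-582-5p (log2 -0.32) also fell. Among the falls, miR-4521 is on the list of entries overlapping other RNA classes. Of 33 named PC-3 calls, 25 held under every alternative and 24 in every omission of 1 library.

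Of 35 tested arms of miRNAs reported as hypoxia-induced in the literature, 9 rose in PC-3, 2 fell and 24 did not pass the test. Adjusted over the list alone the counts were 10 and 2. The risers included miR-210-3p, miR-181c-3p and miR-30b-5p (log2 0.30), and the fallers were miR-181a-3p and miR-181b-3p (log2 -0.75). The list lay higher than the other miRNAs (camera, adjusted p = 0.0064), a call lost with the correlation estimated from the data (adjusted p = 0.138). The miR-17~92 cluster and its paralogues lay lower (adjusted p = 0.0025, 0.138 with estimated correlation). Of 19 tested members 3 fell (miR-92a-1-5p, miR-25-5p and miR-20a-5p, log2 -0.23) and 16 did not pass the test, with 6 lower over the list alone. Both arms counted as members, and the list median (log2 -0.089) was near that of the less abundant arms of 109 hairpins (log2 -0.085). The list test does not separate these. Of 4 p53-regulated miRNAs, miR-192-5p (log2 0.22) and miR-34a-5p (log2 0.30) rose and 2 did not pass the test (3 higher over the list alone). The list's adjusted p was 0.011 (0.164 with estimated correlation), and the miR-34a-5p call was lost in 2 of 9 alternatives (adjusted p up to 0.076). Of 6 smooth muscle or stromal markers, miR-133a-3p (log2 1.23 at 3.0 CPM) and miR-1-3p (log2 0.68) rose and 4 did not pass the test. These 4 were miR-143-3p, miR-145-5p, miR-199a-3p and miR-199b-3p, all highest in the 2 libraries of replicate 1 at 5% O2. All but miR-143-3p passed the count filter only through those libraries. In the other PC-3 libraries miR-145-5p reached at most 0.693 CPM and the miR-199 entries 4.35 CPM. The list test therefore rests in part on these 2 libraries. For miR-1-3p the call was lost in 3 of 9 alternatives (adjusted p up to 0.067). That list's adjusted p of 0.044 became 0.337 with estimated correlation, 0.058 with DESeq2 size factors and 0.153 with the replicate block. With the block the members called over all miRNAs were 12 higher and 6 lower of the hypoxia-induced list, 1 higher and 8 lower of miR-17~92, 3 higher of the p53-regulated list and 2 higher of the smooth muscle or stromal list.

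The other 13 lists tested in PC-3 did not pass the list test (lowest adjusted p 0.094). That lowest value was of the miR-30 family, in which 4 of 11 rose (miR-30b and miR-30d, both arms) and 7 did not pass the test, the same 4 over the list alone. In the let-7 family let-7i-5p rose (log2 0.16), let-7f-1-3p and let-7a-3p fell (log2 -0.30 and -0.28) and 16 of 19 did not pass the test (1 higher and 3 lower over the list alone). In miR-232724, miR-27a-5p rose (log2 0.28), miR-27b-5p fell and 8 of 10 did not pass the test (2 and 1 over the list alone). Of 13 mesenchymal or basal-associated miRNAs, miR-222-5p and miR-221-5p (log2 -0.21) fell and 11 did not pass the test. Of the 11 tested arms of miRNAs reported to target HIF1A, 1 fell (3 over the list alone), and of 7 miR-29 members 1 fell. Of 13 androgen receptor-linked miRNAs 1 rose (1 higher and 2 lower over the list alone). Of 8 neuronal markers 1 fell, as did 3 of 8 entries overlapping other RNA classes (miR-4521, miR-1260a and miR-1260b). None of 7 miR-200, 12 miR-15/16, 8 chromosome 14 cluster or 5 blood or serum members passed the test without the block, over all miRNAs or over the list alone. With the replicate block 1 miR-200 member was called higher and 1 lower, 3 miR-15/16 members and 1 blood or serum marker lower, and no chromosome 14 member. The block also called 4 let-7 members higher and 3 lower, 3 and 2 in miR-232724, 4 and 2 in miR-30, 4 and 2 of the androgen receptor-linked, 2 and 3 of the mesenchymal or basal-associated and 1 and 1 of the neuronal miRNAs. Of those reported to target HIF1A it called 3 lower, of miR-29 1 and of the entries overlapping other RNA classes 3.

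In 22Rv1 the mean effect called 75 of 552 miRNAs, 42 higher and 33 lower. Without the libraries apart on the first principal component, which were picked from these data, the count was 150 (76 higher, 74 lower). With scaling by library size alone it was 46 (20 higher, 26 lower). With the replicate block 164 were called (88 higher, 76 lower), among them 74 of the 75. Besides miR-210-5p, the largest rises by the rule used for PC-3 were in miR-190b, whose gene lies in TPM3 on chromosome 1, and in miR-27a-5p. miR-190b rose 2.48-fold (log2 1.31, standard error 0.14, adjusted p = 8.6e-07, 29.9 to 74.0 CPM, higher in 11 of 11 pairs). miR-27a-5p rose 2.11-fold (log2 1.07, standard error 0.13, adjusted p = 3.1e-06, 29.8 to 67.7 CPM, 10 of 11 pairs). miR-30b-3p rose by log2 0.87 (adjusted p = 1.7e-07, 9 of 11 pairs), and miR-30d-5p from 22914 to 36179 CPM (log2 0.63, adjusted p = 2.2e-06, 10 of 11 pairs). Both arms of miR-152 rose, miR-152-5p by log2 0.73 and miR-152-3p by log2 0.58 (388 to 580 CPM, 11 of 11 pairs). The largest falls by that rule were in miR-4521 (log2 -1.47, standard error 0.29, adjusted p = 0.0029, lower in 11 of 11 pairs, log2 -2.51 to -1.33 over the omissions of 1 library), miR-128-1-5p (log2 -0.74, adjusted p = 0.00019, 11 of 11), miR-7974 (log2 -0.70, 974 to 615 CPM, 11 of 11), miR-33b-3p (log2 -0.68) and miR-191-3p (log2 -0.60, adjusted p = 0.00031, 11 of 11). miR-25-5p (log2 -0.50), let-7f-1-3p (log2 -0.50), miR-30c-1-3p (log2 -0.48), miR-32-3p and miR-193a-5p (log2 -0.47 each) fell as well. Of these falls, that of miR-4521 is of an entry on the list of those overlapping other RNA classes. Of 34 named 22Rv1 calls, 25 held under every alternative (30 with scaling by library size left aside) and 28 in every omission of 1 library.

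The hypoxia-induced list also lay higher in 22Rv1 (adjusted p = 0.00075, 0.256 with estimated correlation). Of its 34 tested members 9 rose, among them miR-210-5p, miR-27a-5p and miR-23a-3p (log2 0.34), 1 fell (miR-195-3p, log2 -0.38) and 24 did not pass the test, with 10 higher and 3 lower over the list alone. In miR-232724, whose loci lie on chromosomes 9 and 19, miR-27a-5p, miR-27a-3p (log2 0.27) and miR-23a-3p rose and 7 of 10 did not pass the test, 4 higher over the list alone (adjusted p = 0.026, 0.256 with estimated correlation). The other 14 lists tested did not pass the list test (lowest adjusted p 0.080). In the miR-17~92 group, miR-25-5p, miR-20a-5p (log2 -0.32), miR-20b-5p (log2 -0.37) and miR-92a-1-5p fell, miR-19a-3p (log2 0.38) and miR-19b-3p (log2 0.28) rose and 15 of 21 did not pass the test (2 higher and 7 lower over the list alone). In the let-7 family let-7b-3p (log2 -0.39), let-7f-1-3p and let-7d-5p (log2 -0.25) fell and 15 of 18 did not pass the test.

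In the miR-30 family of 22Rv1, miR-30b-3p, miR-30d-5p and miR-30d-3p (log2 0.64) rose, miR-30c-1-3p fell and 7 of 11 did not pass the test. Of 14 tested arms of miRNAs reported to target HIF1A 2 fell (1 higher and 2 lower over the list alone). Of 14 androgen receptor-linked miRNAs 2 rose and 2 fell (3 and 2 over the list alone). Of 8 mesenchymal or basal-associated miRNAs miR-22-5p rose (log2 0.37), with 2 higher over the list alone. Of 12 miR-15/16 members 1 fell, of 6 blood or serum markers 1 rose, of 10 neuronal markers 1 rose and 1 fell, and of 12 entries overlapping other RNA classes 2 rose and 1 fell. None of 7 miR-200, 7 miR-29, 5 p53-regulated or 4 smooth muscle or stromal members passed the test over all miRNAs without the block. With the replicate block 15 members of the hypoxia-induced list were called higher and 6 lower, 5 and 1 of miR-232724, 2 and 10 of miR-17~92, 1 and 5 of let-7, 4 and 2 of miR-30, 1 and 4 of those reported to target HIF1A and 6 and 2 of the androgen receptor-linked list. It also called 3 miR-200, 1 p53-regulated, 3 mesenchymal or basal-associated and 3 blood or serum members higher, 3 miR-15/16 members lower, 1 neuronal marker higher and 1 lower, 4 entries overlapping other RNA classes higher and 2 lower, and no miR-29 or smooth muscle or stromal member. The chromosome 14 cluster had 1 member that could be tested in 22Rv1, and the chromosome 19 cluster had none in either line.

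Of 404 miRNAs tested in both lines, 10 rose in both, against 1.63 for independent lists (Fisher p = 3.8e-07). They were miR-210-3p, miR-210-5p, miR-30b-3p, miR-30d-3p, miR-30d-5p, miR-27a-5p, miR-181c-3p, miR-320a, miR-874-3p and miR-874-5p. Another 9 fell in both, against 1.39 (Fisher p = 9.8e-07): let-7f-1-3p, miR-128-1-5p, miR-20a-5p, miR-25-5p, miR-335-3p, miR-33b-3p, miR-4521, miR-551b-5p and miR-92a-1-5p. Both tests take every entry as independent, although arms of one hairpin, such as those of miR-210 and miR-874, are not. The p-values may therefore be too small. miR-181a-3p and miR-1260a fell in PC-3 and rose in 22Rv1. The 22Rv1 call of miR-1260a was lost in 5 of 10 alternatives (adjusted p up to 0.290) and that of miR-181a-3p in 1 of 9 (0.068), and omissions of 1 library ended the miR-1260a call in either line. The mean effects of the 2 lines correlated across miRNAs with r = 0.51 (Spearman 0.35).

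**Figure D2:**
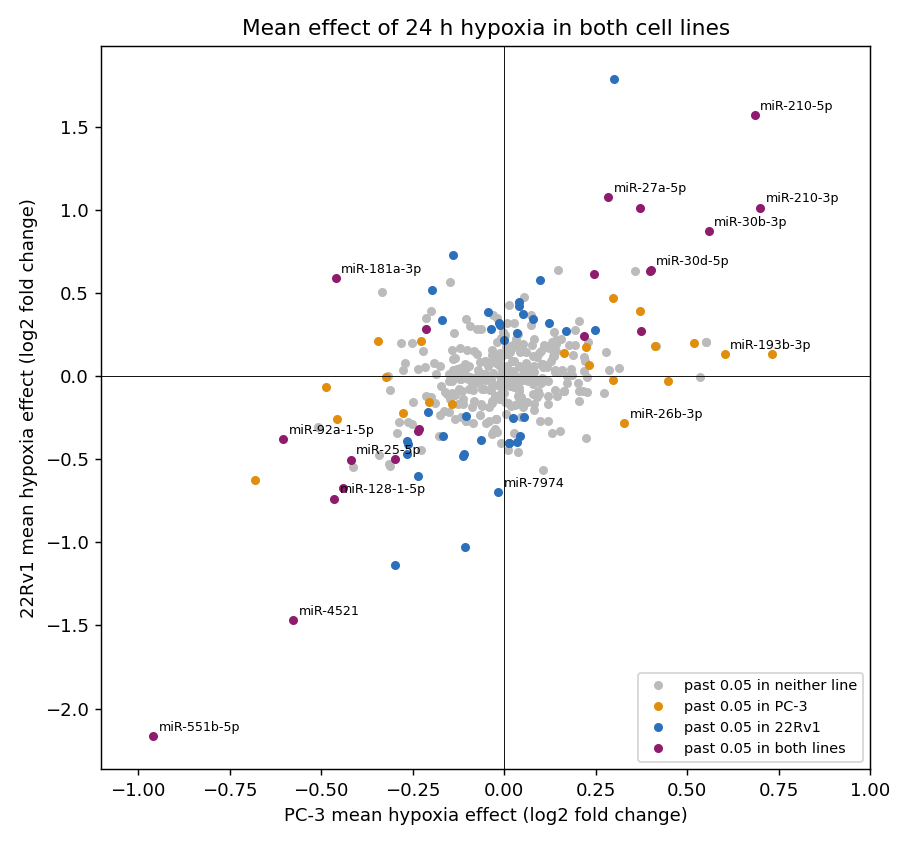
Mean hypoxia effect (log2, over the 6 O2 levels) in PC-3 on the horizontal axis and 22Rv1 on the vertical axis, with 1 point per miRNA tested in both lines and colour giving the lines in which the adjusted p was below 0.05. Of 404 miRNAs 10 rose and 9 fell in both, and the points of miR-30d-5p and miR-30d-3p nearly coincide.

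The mean effect itself differed between the lines for 18 of 613 miRNAs, 3 more positive in PC-3 and 15 more positive in 22Rv1, and for 61 (16 and 45) with the replicate block. With scaling by library size alone the count was 7 (0 and 7), and without 1 library it ranged from 9 to 37. Of 14 named calls, 6 held under every alternative (9 with scaling by library size left aside) and 7 in every omission of 1 library. miR-190b differed by log2 -1.59 (PC-3 minus 22Rv1, adjusted p = 0.0019), miR-181a-3p by -1.07 (adjusted p = 9.3e-05), miR-27a-5p by -0.81 (adjusted p = 0.00029) and miR-582-3p by -0.73 (adjusted p = 9.3e-05). miR-181a-3p went from 327 to 238 CPM in PC-3, lower in 12 of 12 pairs, and from 19.6 to 29.2 CPM in 22Rv1, higher in 10 of 11 pairs. In the other direction stood miR-7974 (log2 0.66, adjusted p = 0.020), miR-26b-3p (0.59, 0.015) and miR-7-5p (0.41, 0.012). miR-4485-3p (log2 -2.53) was at 1.98 CPM and, like miR-1260a and miR-1260b, is on the list of entries overlapping other RNA classes. Smaller differences toward 22Rv1 were seen for miR-1260a (-0.52), miR-1260b (-0.46), miR-19a-3p (-0.44), miR-21-3p (-0.42) and miR-200b-3p (-0.38). Of the 9 alternatives, 3 ended the calls of miR-19a-3p and miR-200b-3p (adjusted p up to 0.138), 2 that of miR-21-3p and 1 each those of miR-1260a and miR-1260b. The miR-232724 list lay lower in PC-3 than in 22Rv1 in this comparison (adjusted p = 0.0017, 0.093 with estimated correlation), with 1 of 10 members passing the test (4 lower over the list alone, and 4 with the replicate block). The hypoxia-induced list had 1 member higher and 4 lower of 36 (1 and 8 with the block) and missed the list test (adjusted p = 0.054, 0.017 with the replicate block and 0.541 with the block and estimated correlation). The other lists missed it too.

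At single O2 levels, with 2 libraries against 2 (2 against 1 in 22Rv1 at 0.2%), fewer miRNAs passed. In PC-3 none of 463 was called at 5% O2 by edgeR (15 at an unadjusted p below 0.05, 0 by DESeq2), 3 at 2%, 3 at 1%, 4 at 0.5%, 7 at 0.2% and 13 at 0%. With the replicate block the counts were 2, 29, 15, 22, 31 and 37, and these held every miRNA called without it. At 2% O2 miR-1908-5p (log2 1.02, adjusted p = 0.042) and miR-210-5p (0.97, 0.015) rose and miR-20a-5p fell (-0.45, 0.042). With all normoxia libraries as control miR-1908-5p stood at log2 0.31 (adjusted p = 0.500), and its call was kept in 2 of 4 omissions of 1 library. The miR-20a-5p call was lost in 5 of 10 alternatives (adjusted p up to 0.210). At 1% miR-92a-1-5p (log2 -1.19, adjusted p = 0.023) and miR-27b-5p (-0.93, 0.042, lost in 5 of 10 alternatives) fell. At 0.5% miR-3919 (1.19, adjusted p = 0.049, lost in 3 of 9) and miR-210-5p (1.15, 0.0019) rose, and at 0.2% miR-210-5p (0.90, 0.010, lost in 1 of 10). miR-210-5p did not pass at 5% (0.33, adjusted p = 0.998), 1% (0.30, 0.962) or 0% O2 (0.45, 0.273, and 0.0447 with the block). At 0% miR-26b-3p rose (0.59, adjusted p = 0.024, lost in 3 of 10) and miR-92a-1-5p (-1.01, 0.024) and miR-128-1-5p (-0.84, 0.024) fell. At 1% no call was left without any 1 of the 4 libraries, and at 0% O2 from 0 to 3 were made. No named call at a single level in PC-3 was kept in every omission of 1 library.

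In 22Rv1 none of 552 was called at 5% O2 by edgeR (19 at an unadjusted p below 0.05, 1 by DESeq2), 2 at 2%, 4 at 1%, 17 at 0.5%, 5 at 0.2% and 26 at 0%. The counts with the replicate block were 1, 7, 24, 107, 16 and 51, again with every miRNA called without it. miR-210-5p rose at 2% (log2 1.48, adjusted p = 0.016), 1% (1.67, 0.0038), 0.5% (1.93, 0.0011), 0.2% (1.93, 0.016) and 0% (1.97, 0.00015), and did not pass at 5% (0.42, adjusted p = 0.985). miR-190b rose at 1% (1.42, adjusted p = 0.030) and 0.2% (1.94, 0.024), and miR-27a-5p at 0.5% (1.51, 0.0071). At 0.2% the control is 1 library, which is assumed to vary like the other groups. miR-191-3p fell at 0.5% (-1.13, adjusted p = 0.014) and 0% (-1.52, 0.00032), miR-128-1-5p at 0.5% (-1.13, 0.035) and miR-33b-3p at 0% (-1.01, 0.045). Of these the calls of miR-190b at 1%, miR-27a-5p, miR-191-3p at 0.5% and miR-33b-3p were lost with scaling by library size alone, and that of miR-128-1-5p without the libraries apart on the first principal component. No named call at 2% or 1% O2 was kept in every omission of 1 library, 1 of 5 was at 0.5%, 1 of 3 at 0.2% and 4 of 5 at 0%. At 0% O2 miR-30b-3p rose 4.63-fold, from 32.9 ± 1.19 to 152 ± 12.6 CPM (n = 2 each, log2 2.21, adjusted p = 8e-08). Without 1 library of the 0% level 12 to 15 calls were made, 11 to 15 of them among the 26, and without the hypoxia library of replicate 1 or 2 at 0.5% O2 the 17 calls became 2 or 36.

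A trend of the effect over the 6 ordered levels, as log2 per step toward lower O2, was called for 1 miRNA in each line, 3 in PC-3 and 17 in 22Rv1 with the replicate block. In 22Rv1 it was miR-30b-3p (slope 0.35, standard error 0.050, adjusted p = 0.00032), with effects of log2 -0.18, 0.77, 0.89, 0.56, 0.99 and 2.21 from 5% to 0% O2. Over the 5 levels above 0% O2, on a log2 scale of O2, its adjusted p was 0.65. In PC-3 it was miR-4461 (slope -0.63, from log2 1.26 at 5% to -2.34 at 0% O2), a miRNA below 20 CPM. The slopes of miR-210-3p (0.06 in PC-3, 0.05 in 22Rv1, adjusted p = 0.995 and 0.856) and of miR-210-5p (0.03 and 0.27, adjusted p = 0.995 and 0.191) did not pass. With the block the miR-210-5p slope in 22Rv1 was 0.30 (adjusted p = 0.00067). No list passed the trend test (17 lists in PC-3, lowest adjusted p 0.107 for the hypoxia-induced list, and 16 in 22Rv1, lowest 0.051 for the androgen receptor-linked list). With the block these 2 values were 0.020 and 0.0028, and 0.372 and 0.628 with the block and estimated correlation.

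**Figure D3:**
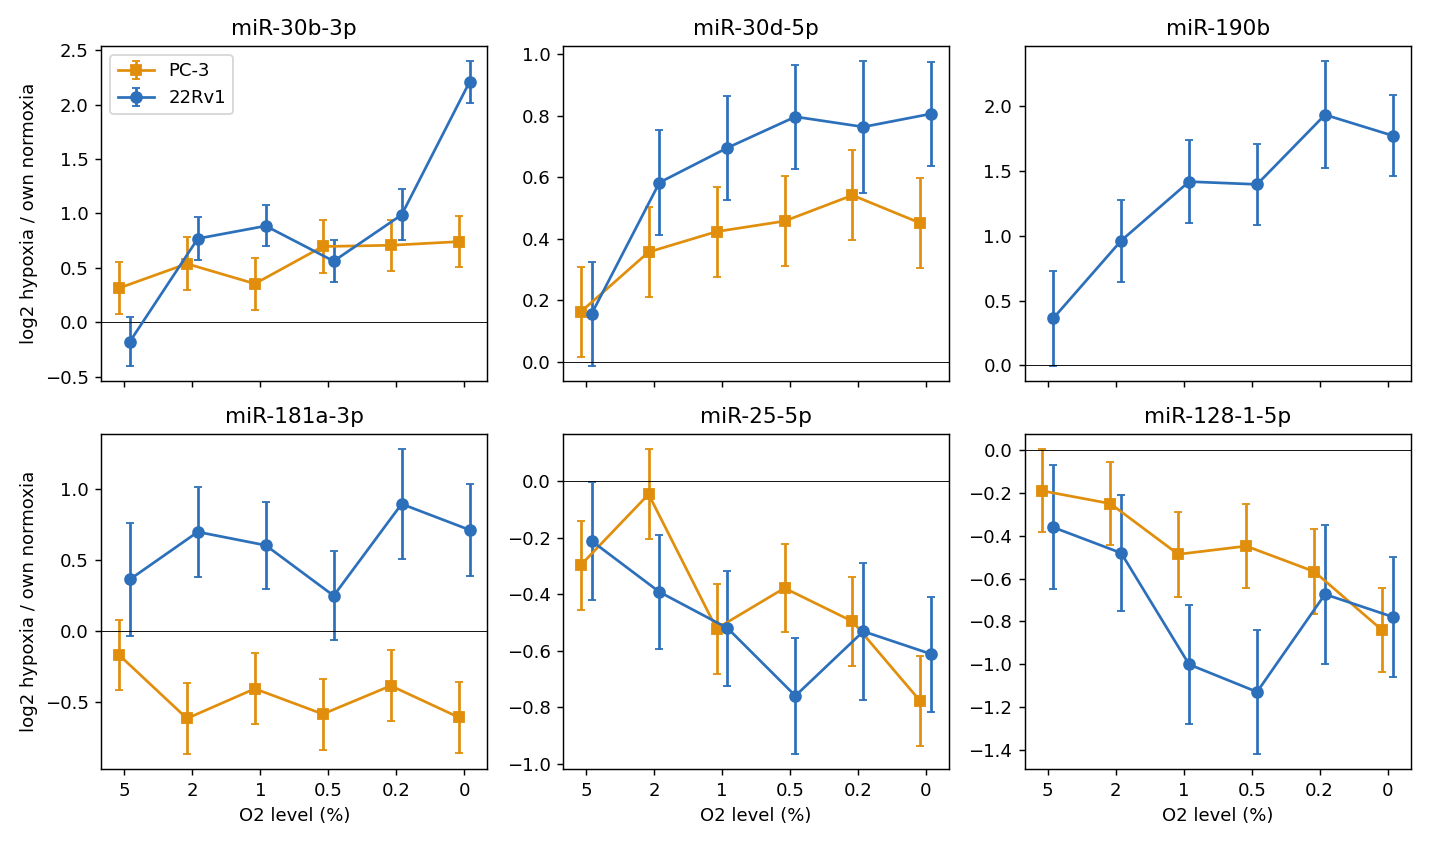
Hypoxia effect (log2 against the normoxia control of the same level, bars are standard errors) by O2 level for selected miRNAs in PC-3 and 22Rv1, with miR-190b drawn for 22Rv1 alone because it was not tested within PC-3. miR-30b-3p in 22Rv1 stands at 2.21 at 0% O2.

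The lines themselves differed far more than hypoxia changed either. In normoxia 527 of 613 miRNAs differed between PC-3 (12 libraries) and 22Rv1 (11 libraries), 243 higher in PC-3 and 284 lower. miR-100-5p, from the MIR100HG locus with let-7a-2 and miR-125b-1, was at 35140 ± 4017 CPM (SD) in PC-3 and 0.509 ± 0.363 in 22Rv1 (log2 16.03), and miR-125b-5p at 5039 and 20.4 CPM (log2 8.03). The linked miR-221-3p (log2 9.70) and miR-222-3p (log2 9.24), miR-31-5p (log2 9.21), miR-130a-3p (log2 10.6) and miR-21-5p (159900 against 8432 CPM, log2 4.23) were also higher in PC-3. miR-125b-1-3p had no counts in 22Rv1 and was at least 13380-fold higher in PC-3. miR-100-3p had 3 counts in 22Rv1, a ratio of 22849 (95% counting interval 7818 to 110798). miR-363-3p (log2 -10.7), miR-141-3p (log2 -10.4), miR-200c-3p (22.4 against 20529 CPM, log2 -9.85), miR-148a-3p (428 against 50755 CPM) and miR-20b-5p (log2 -5.40) were lower in PC-3. miR-598-3p and miR-383-5p had no counts in PC-3 normoxia and were at least 571-fold and 518-fold higher in 22Rv1.

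The 2 loci of the miR-200 family, which maintains epithelial identity, went in opposite directions. The chromosome 1 members miR-200b-3p (6474 against 49.3 CPM, log2 7.04), miR-200a-3p (1856 against 37.9 CPM) and miR-429 (log2 6.41) were higher in PC-3 and the chromosome 12 members miR-200c and miR-141 in 22Rv1, with 5 of the 9 arms tested higher and 4 lower. These directions were the same under every scaling tried. Of 14 mesenchymal or basal-associated miRNAs 13 were higher in PC-3 and 1 lower (list adjusted p = 7e-07, 0.010 with estimated correlation). Of 10 miR-232724 members 9 were higher, among them miR-24-3p (log2 2.58), miR-27a-3p (log2 2.56) and miR-23a-3p (log2 2.42), and 1 did not pass the test (list adjusted p = 0.0060, 0.129 with estimated correlation). No other list passed the list test here, the lowest being miR-29 (4 higher, 3 lower of 7, adjusted p = 0.057). Its value was 0.041 with DESeq2 size factors and 0.531 with estimated correlation. Single members still differed in most lists: 20 higher and 13 lower of 36 hypoxia-induced miRNAs, 9 higher of 11 miR-30 members, 7 higher of 8 in the chromosome 14 cluster, and 7 higher and 8 lower of 15 androgen receptor-linked miRNAs. miR-210-3p was lower in PC-3 normoxia (log2 -0.79), as was miR-210-5p (log2 -0.26, adjusted p = 0.0252), whose call was lost in 2 of 9 alternatives (adjusted p up to 0.201). This comparison was scaled over all libraries. The CPM given for miR-210 with the hypoxia effect were scaled within each line and do not give these ratios.

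**Figure D4:**
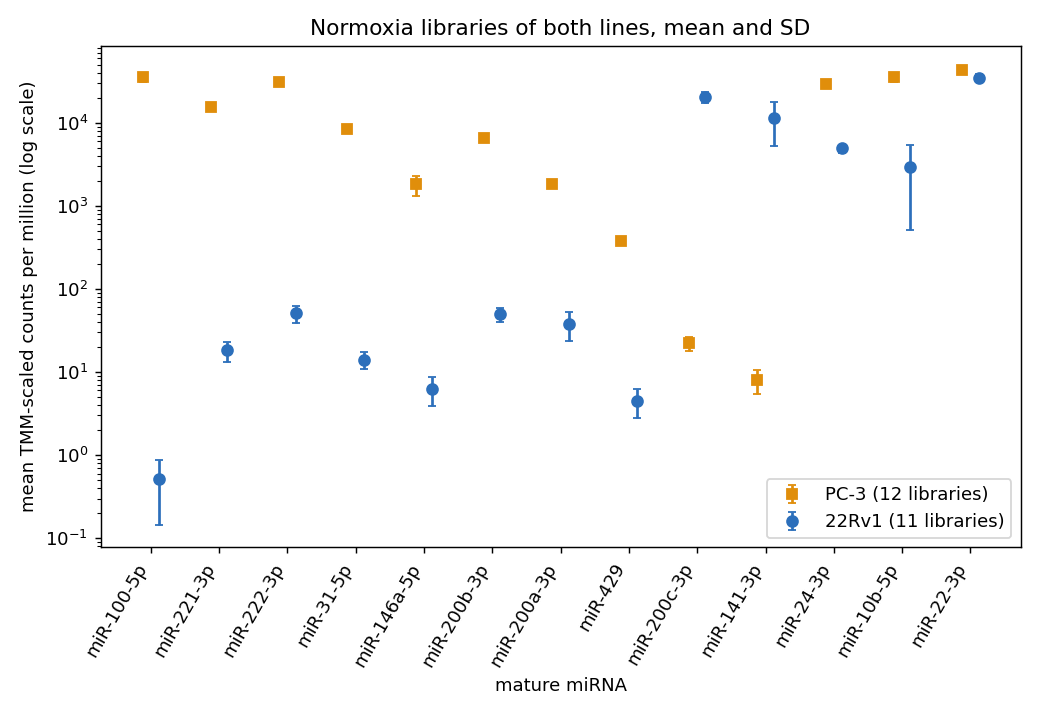
Mean CPM (log axis, bars are SD) of selected miRNAs in normoxia in PC-3 (12 libraries) and 22Rv1 (11 libraries). miR-200b-3p is higher in PC-3 and miR-200c-3p in 22Rv1.

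The normoxia control sets of the 6 levels were compared within each line. By the edgeR test over all sets 0 of 463 miRNAs were called in PC-3 (13 at an unadjusted p below 0.05, 2 by DESeq2). In 22Rv1 0 of 552 were called (3 at an unadjusted p below 0.05, 0 by DESeq2). Both unadjusted counts are fewer than that threshold gives with no difference at all. The edgeR test was thus conservative here, and the absence of calls does not show the sets to be alike.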

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

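The regrouping tests given here were planned before the results were seen, and the alternative settings quoted beside them are those of the next part. The results below stood out because a change differed between the lines or between the O2 levels.

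The mean hypoxia effect differed between the lines for 18 miRNAs. miR-190b (log2 -1.59, PC-3 minus 22Rv1), miR-181a-3p (-1.07), miR-210-5p (-0.90), miR-27a-5p (-0.81) and miR-582-3p (-0.73) changed more positively in 22Rv1, and miR-7974 (0.66), miR-26b-3p (0.59) and miR-7-5p (0.41) in PC-3. Of these 8, miR-190b lost its call without the PC-3 normoxia library of replicate 1 at 2% O2 (adjusted p = 0.230) and miR-7974 without the 22Rv1 hypoxia library of replicate 1 at 5% O2 (adjusted p = 0.0502). miR-190b did not pass the count filter within PC-3, so it has no test of its own in that line. Over the 9 alternatives miR-7974 lost its call in 2 (adjusted p up to 0.081), miR-7-5p in 2 (up to 0.084) and miR-26b-3p in 1 (0.138), and the 5 toward 22Rv1 in none. With the line exchanged for whole pairs within a level, and pairs as a block without level terms, the real grouping called 53 miRNAs. It was the 1 of 100 groupings with as many calls (highest other 9). This speaks against chance for the count of 53 in that model, and does not test the 18 calls or any single miRNA.

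For the mean effect in PC-3, exchanges of hypoxia and normoxia within pairs gave as many calls as the 51 in 1 of 100 groupings, the real one, with 7 as the highest other count. For 22Rv1 the real count of 75 was also reached in 1 of 100, with 55 as the highest other. That grouping exchanged the 2 pairs at 5% O2 alone and so kept the other levels as they were. For PC-3 against 22Rv1, tested in the normoxia libraries alone, the real grouping called 510 miRNAs and was the 1 of 100 with as many. The highest other, 463, exchanged 20 of the 23 labels and so nearly mirrored the real one. For these 3 results this speaks against chance for the number of calls, and does not test any single miRNA.

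The slope of miR-4461 over the O2 levels in PC-3 was -0.63 (log2 per step), at a level of about 4 CPM. No slope was called in PC-3 in 11 of 24 omissions of 1 library, which the next part names. The slope of miR-30b-3p in 22Rv1 was 0.35 and held in every omission of 1 library, and it was 0.20 per log2 of O2 without the 0% level (adjusted p = 0.65, range over the alternatives 5.1e-07 to 0.65).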

How the results depend on the processing

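The alternatives were chosen before the data were examined, except the authors' scaling factors, identical entries kept once and the omission of libraries apart on the first principal component, which were added after the results were seen. Of 201 named results, 166 kept their call and direction under every alternative except scaling by library size alone, and 35 lost or gained a call or turned in 1 or more. Counts at single levels rest on 2 libraries against 2 (2 against 1 in 22Rv1 at 0.2%) and moved with most choices. The mean effect over 6 levels moved by over 1.5 times with the replicate block in both lines, and in 22Rv1 with 3 further choices given below. Values below are numbers of miRNAs called.

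The replicate number as a block moved most counts upward. In PC-3 the counts from 5% to 0% O2 were 2, 29, 15, 22, 31 and 37, the mean effect 109 and the trend 3. In 22Rv1 they were 1, 7, 24, 107, 16 and 51, the mean effect 164 and the trend 17. The line difference had 61. List calls with the block were 1 for the PC-3 trend, 1 for the 22Rv1 trend and 2 for the line difference, and none of these held with estimated correlation (lowest adjusted p 0.372, 0.628 and 0.246). Beyond the smooth muscle list in PC-3 and 1 call each in the 22Rv1 mean effect and the normoxia comparison it ended no call. With all normoxia libraries of a line as control, PC-3 had 3, 7, 21, 21, 25 and 32 calls from 5% to 0% O2, and 22Rv1 had 6 at 2%, 27 at 1%, 47 at 0.5%, 39 at 0.2% and 50 at 0%.

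With DESeq2, PC-3 had 10 calls at 2% O2, 11 at 0.2% and 2 between control sets, and 22Rv1 had 1 at 5%, 10 at 1%, 11 at 0.2% and 4 for the trend. With DESeq2 size factors in edgeR, PC-3 had 1 at 1% and 3 at 0.2%. With the authors' scaling factors, PC-3 had 5 at 2% (5 higher, 0 lower), 1 at 1%, 1 at 0.2%, 8 at 0% (0 higher, 8 lower) and 2 for the trend, and 22Rv1 had 3 at 0.2% and 3 for the trend. The slope of miR-210-5p in PC-3 turned to -0.0034 there. The authors' factors shifted the median of all miRNAs in PC-3 by log2 -0.13 at 0.2% and -0.11 at 0% O2.

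With scaling by library size alone, PC-3 had 2 calls at 0.5% O2, 4 at 0.2%, 8 at 0% (0 higher, 8 lower) and 66 for the mean effect (22 higher, 44 lower). 22Rv1 had 1 at 2%, 1 at 1%, 7 at 0.5% (2 higher, 5 lower), 3 at 0.2% (3 higher, 0 lower), 9 at 0% (7 higher, 2 lower), 46 for the mean effect (20 higher, 26 lower) and 0 for the trend. The line difference had 7 (0 higher, 7 lower) and the normoxia comparison 532 (180 higher, 352 lower). The medians of all miRNAs in 22Rv1 stood at log2 0.12 at 2%, -0.39 at 0.5%, 0.11 at 0.2% and -0.14 at 0% O2, and at -0.60 in the normoxia comparison (-0.15 with TMM).

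With no low-count filter, PC-3 had 2 calls at 0.2% O2 and 8 at 0%, and the 22Rv1 trend 2. With a filter at 50 CPM, PC-3 had 0 at 1% and 0 for the trend, and 22Rv1 had 47 for the mean effect and 2 for the trend, and the normoxia comparison had 290. With identical entries kept once, PC-3 had 1 at 1% and 2 at 0.5%, and the 22Rv1 trend 2. Without the libraries apart on the first principal component, PC-3 had 1 at 2%, 2 at 0.5%, 3 at 0.2% and 0 for the trend, and 22Rv1 had 10 at 2%, 29 at 1%, 27 at 0.5%, 17 at 0.2%, 57 at 0%, 150 for the mean effect (76 higher, 74 lower) and 12 for the trend, with 3 list calls for the 22Rv1 trend. The trend without the 0% level had 0 calls in PC-3 and 0 in 22Rv1, and the trend over hypoxia libraries alone 2 and 13. With estimated list correlation the list calls were 0 for the PC-3 mean effect, 0 for the 22Rv1 mean effect, 0 for the line difference and 1 for the normoxia comparison.

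Where an omission left 1 library in a group, it is assumed to vary like the other groups. Without the only 22Rv1 control at 0.2% O2 that level dropped out. The 22Rv1 mean effect, which had its lowest count there, and the 22Rv1 trend were then over 5 levels. In that fit the line difference set 6 PC-3 levels against 5, and the normoxia comparison used 5 control sets per line. Leaving out 1 library at a time, calls in PC-3 ranged from 0 to 1 at 5% O2, 0 to 6 at 2%, 0 to 0 at 1%, 0 to 12 at 0.5%, 0 to 5 at 0.2% and 0 to 3 at 0%, from 41 to 63 for the mean effect, from 0 to 3 for the trend and from 0 to 1 between control sets. In 22Rv1 they ranged from 0 to 1 at 5%, 0 to 3 at 2%, 0 to 2 at 1%, 2 to 36 at 0.5%, 1 to 7 at 0.2% and 12 to 15 at 0%, from 51 to 103 for the mean effect, from 1 to 8 for the trend and from 0 to 2 between control sets. The line difference ranged from 9 to 37 and the normoxia comparison from 512 to 528. At single levels each library of the level moved the count by over 1.5 times or ended it, except hypoxia 1 and normoxia 2 in PC-3 at 5%, normoxia 1 in PC-3 at 0.5%, hypoxia 2 in PC-3 at 0.2%, hypoxia 1 and normoxia 1 in 22Rv1 at 5%, hypoxia 1 in 22Rv1 at 2% and hypoxia 2 in 22Rv1 at 0.2%.

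The PC-3 trend had 0 calls without replicate 1 of hypoxia at 5, 2, 0.2 or 0% O2 or of normoxia at 5, 2 or 0.2%, and without replicate 2 of hypoxia at 1 or 0% or of normoxia at 5 or 0%. It had 3 and 2 without replicate 2 of hypoxia at 2 and 0.5%. The 22Rv1 trend had 4 calls without hypoxia 1 or normoxia 2 at 5%, normoxia 1 at 0.2% or hypoxia 2 at 0.5%, 3 without normoxia 1 at 5% or hypoxia 1 at 0.2%, 2 without hypoxia 1 at 0.5%, and 8 without hypoxia 2 at 0.2%. The line difference had 9 calls without the PC-3 library normoxia 1 at 2% or normoxia 2 at 0.5%. It had 10 or 11 without PC-3 normoxia 1 at 5%, hypoxia 2 at 1, 0.2 or 0% or normoxia 2 at 1, 0.2 or 0%, and without 22Rv1 hypoxia 1 at 5, 2, 1 or 0.2%, normoxia 1 at 1%, hypoxia 2 at 2% or normoxia 2 at 2 or 1%. It had 32 without the 22Rv1 hypoxia library 2 at 5% and 37 without that at 0.2%.

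Single omissions ended 9 of the 33 named calls for the PC-3 mean effect: miR-582-5p, let-7i-5p, let-7f-1-3p, let-7a-3p, miR-34a-5p, miR-221-5p, miR-1-3p, miR-1260a and miR-1260b, with adjusted p up to 0.080 for miR-582-5p. They ended 6 of 34 for 22Rv1: miR-27a-3p, let-7d-5p, miR-148a-5p, miR-126-5p, miR-128-3p and miR-1260a. For the line difference they ended 7 of 14: miR-190b, miR-7974, miR-19a-3p, miR-200b-3p, miR-21-3p, miR-4485-3p and miR-1260b. In normoxia they ended 2 of 74, miR-210-5p (adjusted p = 0.0503 without the PC-3 normoxia library 1 at 0%) and miR-451a (without the 22Rv1 normoxia library 2 at 5%). The mean effect on miR-4521 in 22Rv1 was log2 -2.51 without the hypoxia library 2 at 0.5%, which leaves that group with a library without counts of it, and it stayed called in 23 of 23 omissions.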

Other observations

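miR-30d-5p had a positive effect at each of the 6 O2 levels in both lines, log2 0.16 at 5% O2 and 0.45 at 0% in PC-3, and 0.16 and 0.81 in 22Rv1. At single levels it passed the test only in 22Rv1, at 0.5% (adjusted p = 0.0137) and 0% O2 (0.0050). From the same locus miR-30b-5p rose in PC-3 (5216 to 6426 CPM, log2 0.30, 12 of 12 pairs) and did not pass the test in 22Rv1 (log2 0.47, adjusted p = 0.119, 9 of 11 pairs). miR-320a rose modestly in both lines (log2 0.22 and 0.24, higher in 12 of 12 and 11 of 11 pairs). miR-335-3p fell in both (log2 -0.23 and -0.33, lower in 11 of 12 and 10 of 11 pairs). miR-551b-5p, below 20 CPM, had the lowest mean effects among the shared calls (log2 -0.96 in PC-3 and -2.17 in 22Rv1, lower in 11 of 12 and 10 of 11 pairs).

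Normoxia levels of further cancer-related miRNAs differed between the lines. miR-146a-5p stood at 1820 CPM in PC-3 and 6.31 in 22Rv1, miR-10b-5p at 35047 and 2960, and miR-29a-3p at 6036 and 193. miR-34a-5p, a p53 target, stood at 29.4 CPM in PC-3 and 262 in 22Rv1. miR-195-5p was lower in PC-3 (log2 -4.00). miR-4461 fell in 22Rv1 at 0.2% O2 (log2 -2.88, adjusted p = 0.0456) and at 0% O2 in PC-3 (log2 -2.34, adjusted p = 0.0398). It did not pass in 22Rv1 at 0% (log2 -0.60, adjusted p = 0.712) or in PC-3 at 0.2% (-0.91, 0.538), and the 22Rv1 control at 0.2% is 1 library.

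Of the tests below, those on the arms of hairpins were written before their values were computed but after the pattern had been noticed among the named miRNAs, and those on single libraries and on miR-143-3p were chosen after the values were seen, except thinning to equal depth. The ratio in the test of PC-3 RNA was restricted to libraries with miR-100-5p above the median of the others, because 1 library had no counts of it. For the arms in 22Rv1 the written prediction counted an exact p of 0.05 or more as a point for scaling, and this was changed to an open result after the value was seen, since a missed threshold leaves open whether there is a difference at all.

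The less abundant arm of a hairpin fell relative to the abundant arm in PC-3. Over 109 hairpins whose arms differed in abundance by a log2 ratio of at least 1, the median difference of the mean effects was log2 -0.081 (lower in 79, negative in 12 of 12 pairs, exact two-sided p = 0.0024), which a scaling factor per library cannot give, and 0% of 10000 random lists matched on abundance were as low. In 22Rv1 the median over 121 hairpins was -0.060 (lower in 72, 10 of 11 pairs, exact p = 0.081), which leaves open whether there is a difference in 22Rv1, although a factor per library cancels within a hairpin there too. In 22Rv1 0.14% of matched lists were as low. Of 91 such hairpins in both lines with the same less abundant arm, 43 were lower in both and 12 higher in both (r = 0.43 across hairpins). The cause remains open.

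In 22Rv1 the libraries of replicate 1 at 5% O2 (hypoxia and normoxia) and the hypoxia library of replicate 1 at 0.5% O2 lay at the low end of the first principal component, with miR-193a-3p at 139, 47.9 and 117 CPM against 262 to 1738 in the 20 others and miR-138-5p at 149, 82.3 and 149 against 297 to 774. These CPM were scaled by library total alone, and the TMM factors of the 3 libraries within 22Rv1 were 0.817, 0.698 and 0.766. Lower depth could not account for their position, since 3 of the 3 stayed outside the range of the others after thinning to 960421 counts. RNA from PC-3 could not either: miR-10b-5p would need a PC-3 share at least 101 times that allowed by miR-100-5p. In the hypoxia library of replicate 1 at 5% O2 miR-100-5p was at 36.7 CPM, against at most 4.37 in the 20 others. That would be a PC-3 share of 0.12%. Entries overlapping other RNA classes took a larger share than in every other library in 1 of the 3. The source of the difference remains open.

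miR-143-3p stood at 1184 and 1281 CPM in the PC-3 hypoxia and normoxia libraries of replicate 1 at 5% O2, against at most 26.6 in the 22 others. Carry-over from 22Rv1 libraries, judged by miR-141-3p, gives at most 0.064% of the excess. Of 7 other smooth muscle or stromal markers 3 were above every other PC-3 library in both (miR-145-5p at 6.79 and 5.90 CPM against at most 0.693, and miR-199a-3p and miR-199b-3p, which share their counts, at 13.6 and 7.99 against at most 4.35), while miR-1-3p and miR-133a-3p were not, and 5 of the 7 had a median above 0 in the other PC-3 libraries. The share of blood or serum markers was raised in 0 of the 2 libraries. RNA from stromal cells may therefore contribute. miR-145-5p stayed far below miR-143-3p, but it did so in 22Rv1 as well (medians 1.13 and 153 CPM), so this gap does not decide the question. The source remains open.

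In the 22Rv1 hypoxia library of replicate 1 at 5% O2 miR-143-3p was at 10.6 CPM, against 97.7 to 200 in the 20 libraries not at the low end. The other libraries at the low end had 174 (normoxia of replicate 1 at 5%) and 443 CPM (hypoxia of replicate 1 at 0.5%). The 22Rv1 hypoxia library of replicate 2 at 0.2% O2 lay at the high end of the first component (score 6.19). In PC-3 the 2 libraries of replicate 1 at 5% O2 lay apart, at -5.01 and -5.19.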
